A study of Mus musculus with 10 samples.

How the data were processed

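Single-cell RNA libraries were prepared with 10x Chromium 3' v3 chemistry from KPPC mouse pancreatic tumours, per the labels' protocols. There were 10 libraries: 6 of CD45+ cells and 4 of a CAF-enriched gate. The deposited values were UMI counts per gene and cell barcode, made with Cell Ranger 4.0.0 on mm10 per the submitters' processing notes. Each matrix listed 32285 genes, and gene names were taken from the gene lists deposited with it. The files held whole numbers with at least 500 UMIs per barcode and no cell annotation.

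Cells were kept with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs, which kept 71.5% to 93.5% of barcodes and lost 6.21% to 28.4% to the mitochondrial limit. Scrublet scores were computed with its implementation in scanpy 1.11.5. Its automatic threshold marked 0 to 2 cells in 6 libraries, so the cells with the highest scores were removed instead, at an expected rate of 0.8% per 1000 cells (4.07% to 19.0% of cells). Counts were scaled, log-transformed, reduced to 30 principal components of 2000 variable genes and clustered with leidenalg 0.10.2 (15 neighbours, resolution 0.8), separately for each gate and with no batch integration. Mitochondrial, ribosomal, sex-linked, immunoglobulin, T-cell receptor and haemoglobin genes and unnamed gene models were left out of the variable genes. This gave 45 clusters of 50547 CD45+ cells and 33 clusters of 55314 CAF-gate cells.

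Clusters were called X-like from markers fixed before the data were examined, when at least 3 markers were among the top 50 genes by fold that at least 25% of cells held. Clusters that failed against their own gate were tried again against the clusters of both gates. This retry named macrophage-like clusters 1, 11, 12 and 38, T-cell-like 21 and 33, B-cell-like 19 and 24 and all CAF-gate fibroblast-like clusters. A cluster of few UMIs without a marker among its top 10 genes, or with at least 5 markers of another class, stayed unnamed. So did a cluster with more markers of another class among its top 10 genes, a tie or fewer than 20 cells. Clusters 8 (best class macrophage) and 40 (T cell) of the CD45+ gate were unnamed because other markers led them. A further limit, a median UMI count under 1/5 of the gate's, was set after seeing the data, with neutrophil-like clusters exempt. It kept CD45+ clusters 13, 18, 32 and 35 and 3 CAF-gate clusters unnamed. Without it the rule named the former macrophage-like, acinar-like, fibroblast-like and macrophage-like, and CAF-gate clusters 1 and 16 acinar-like and 6 fibroblast-like. The 3 CAF-gate clusters held 36.4%, 17.6% and 5.07% of the cells of the RT plus FAK inhibitor library, and their unnamed total was under 0.350% in the other CAF-gate libraries. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only, as do the exact Poisson intervals of sums and ratios.

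For immune cells raw counts were summed per library and class and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, its filter on low counts and 1 coefficient per treatment over all groups. Macrophage-like, monocyte-like, neutrophil-like, T-cell-like and conventional-dendritic-cell-like cells were tested, on 15179, 11079, 10503, 12041 and 11050 genes. The class sums per library held 1119879 to 67516985 UMIs. Vehicle replicates 2 and 3 were summed as 1 sample, so vehicle had 2 samples and the residual had 1 degree of freedom, moderated across genes. The prior degrees of freedom estimated for that were 3.55, 12.2, 61.3, 38.4 and 55.6 in the 5 classes. p-values were two-sided and adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Fixed gene lists, 42 in all, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated one, and with fry. On simulated counts camera with an estimated correlation gave a fully changed 20-gene list p values of 0.0321 to 0.0514. A list could therefore hardly pass with it after adjustment, and a high adjusted p there does not argue against a list. DESeq2 1.42.0 was run as an alternative.

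For fibroblast-like cells each group had 1 library, so no test was made. CPM were compared as ratios, genes were counted when at least 2-fold apart with at least 50 CPM in the higher library and an interval that excluded 1, and each list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression. The fibroblast sums held 185346912, 115748659, 171005757 and 78677352 UMIs for vehicle, RT, FAK inhibitor and both.

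The genes the text names were chosen by a rule fixed before the data were examined. It took Ptk2 and Ptk2b. In immune classes it took the 5 highest and 5 lowest genes per comparison among those called, with an absolute log2 fold change of at least 1, at least 50 CPM in the higher group and a treated value outside the range of the vehicle libraries. In fibroblasts it took the 10 highest and 10 lowest counted genes, and for each described list up to 4 members and the most extreme member the other way. Ribosomal, mitochondrial, receptor segment, haemoglobin, sex-linked and unnamed genes were left out, as were genes over 10 times higher in another class of the same gate in every library compared. Genes that were so in only some of the libraries compared could be named.

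The tests were checked on simulated counts. For RT against vehicle edgeR recovered 43.3%, 91.0%, 89.6%, 77.6% and 79.1% of genes changed 4-fold in the 5 classes, in the order above, with 4 to 10 false calls. The fibroblast ratio rule counted 65 of 67 genes changed 3-fold for RT and none of 67 changed 1.5-fold. Alternatives, among them means over cells and TMM scaling, are given with the results they moved in the section on processing. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 was used for the rest.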

Results

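Single-cell RNA libraries were made from pancreatic tumours of KPPC mice, a genetically engineered model of pancreatic ductal adenocarcinoma. The mice received vehicle, radiation therapy (RT, 5 fractions of 6 Gy), the focal adhesion kinase (FAK) inhibitor VS-4718 (75 mg per kg, 2 doses per day) or both. The design asked how RT and FAK inhibition, alone and together, altered the immune cells and the cancer-associated fibroblasts (CAFs) of these tumours. There were 6 libraries of CD45+ cells, of which 3 came from vehicle and 1 from each treated group, and 4 libraries of a CAF-enriched gate, 1 per group. Each CD45+ library held between 80292710 and 175265474 UMIs, and each CAF-gate library between 117482993 and 256787451 UMIs. After filters and doublet removal, 4567 to 14839 cells remained per CD45+ library and 9710 to 18114 per CAF-gate library. The median UMI count per kept cell was 1651 in the RT plus FAK inhibitor CAF-gate library, against 11746 to 14114 in the other CAF-gate libraries.

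Vehicle CD45+ replicates 2 and 3 held the same mix of cell classes within sampling noise (chi-square 12.1, against a mean of 13.3 over 200 random re-splits of their pooled cells, permutation p = 0.537). Over genes their median chi-square was 1.02, slightly above the re-split maximum of 0.818, while the pairs with replicate 1 reached 39.4 and 38.1. In the plan fixed before the data were examined the 3 vehicle libraries were separate samples. After this comparison replicates 2 and 3 were counted as 1 sample, which left 2 vehicle samples. The labels did not tie libraries to animals, so p-values measured only the spread between these samples, and each treated library was assumed to vary as the vehicle samples did. Treatment could not be separated from library or animal, and only in part from sex. All typed cells of vehicle replicate 1 and the vehicle CAF-gate library held Xist, with Y-linked transcripts in 1 and 3 of them, nearly all those of vehicle replicates 2 and 3 and both RT plus FAK inhibitor libraries held Y-linked transcripts without Xist, and the other libraries were mixtures.

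The gene of the drug target, Ptk2 (FAK), was at similar levels in fibroblast-like cells of all 4 groups. It stood at 29.3 CPM in vehicle (95% exact counting interval 28.5 to 30.1), 27.2 after RT (26.2 to 28.1), 30.7 after FAK inhibitor (29.9 to 31.6) and 28.9 after both (27.7 to 30.1). Ptk2b, which encodes the related kinase PYK2, stood at 11.9, 10.5, 6.84 and 8.15 CPM in the same order. These transcripts do not check the labels, since a kinase inhibitor need not alter them. In immune cells Ptk2b was the more abundant of the pair, at 41.2 to 47.2 CPM in macrophage-like and 54.2 to 77.1 CPM in T-cell-like cells across samples, where Ptk2 stood at 1.99 to 6.28 and 3.8 to 5.06 CPM.

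The immune mix of the FAK inhibitor library was dominated by lymphocytes. T-cell-like cells made up 46.6% of its CD45+ cells (95% exact binomial interval 45.8 to 47.4), against 10.9% ± 3.75 in vehicle (SD, n = 2), and B-cell-like cells 38.2% (37.4 to 39.0) against 15.8% ± 1.91. Macrophage-like cells made up 3.79% (3.49 to 4.11) against 33.9% ± 11, neutrophil-like cells 1.60% (1.41 to 1.82) against 10.7% ± 0.248, and monocyte-like cells 0.472% (0.368 to 0.596) against 7.39% ± 1.97. Unnamed cluster 8, with 5 macrophage markers but led by markers of other classes, held 14.05% of vehicle replicate 1 and 0.259% and 0.225% of replicates 2 and 3. Counted as macrophage-like it brought the vehicle share to 41.1% ± 1.25 and the RT share to 23.9%. The RT plus FAK inhibitor library lay between these extremes for lymphocytes, with 25.9% B-cell-like (25.0 to 26.8) and 15.2% T-cell-like cells (14.4 to 15.9). It also held 6.90% plasma-cell-like cells (6.39 to 7.44) against 2.01% ± 0.0897 in vehicle, and 3.8% ILC2-like cells (3.42 to 4.21), the innate source of type 2 cytokines, against 0.218% ± 0.00833. After RT alone, T-cell-like (13.2%, 12.2 to 14.2) and plasma-cell-like shares (2.23%, 1.82 to 2.70) lay within or near the vehicle range. Macrophage-like cells were at 20.0% (18.9 to 21.2) after RT and at 19.8% (19.0 to 20.6) after RT plus FAK inhibitor. The RT value depended on the limit on UMIs set after seeing the data, which left cluster 13 (best class macrophage) unnamed. It held 16.3% of the RT library and 1.09% to 1.93% of vehicle. Without the limit macrophage-like cells were at 36.6% after RT and 36.0% ± 9.81 in vehicle, and at 19.9% after RT plus FAK inhibitor. A lower macrophage share after RT is therefore not claimed.

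Within T-cell-like cells, regulatory-like cells made up 9.53% (8.84 to 10.2) in the FAK inhibitor library against 16.3% ± 2.83 in vehicle, and cells of the gamma-delta or IL-17 type 1.52% (1.24 to 1.83) against 9.58% ± 4.87. The latter made up 15.0% (13.1 to 17.0) after RT plus FAK inhibitor, near the 12.6% and 13.4% of vehicle replicates 2 and 3, and 4.98% after RT. CD8-like cells made up 24.5% after FAK inhibitor, 9.36% after RT plus FAK inhibitor and 16.8% ± 6.11 in vehicle. Shares sum to 100%, so a gain in 1 class lowers the others. Intervals cover counting error only, and no test of shares between groups was made. In the RT library 29.3% of cells stayed unnamed, mostly in clusters with few UMIs per cell, against 10.4% ± 11.7 in vehicle, where most came from cluster 8 of replicate 1. Among stricter cells the unnamed share was 6.34% after RT and 8.26% ± 10.4 in vehicle. Among these cells the B-cell-like share after RT lay 0.871 percentage points above the vehicle mean, where it lay below it in the main data, and after RT plus FAK inhibitor it lay 1.43 points above.

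**Figure D1:**
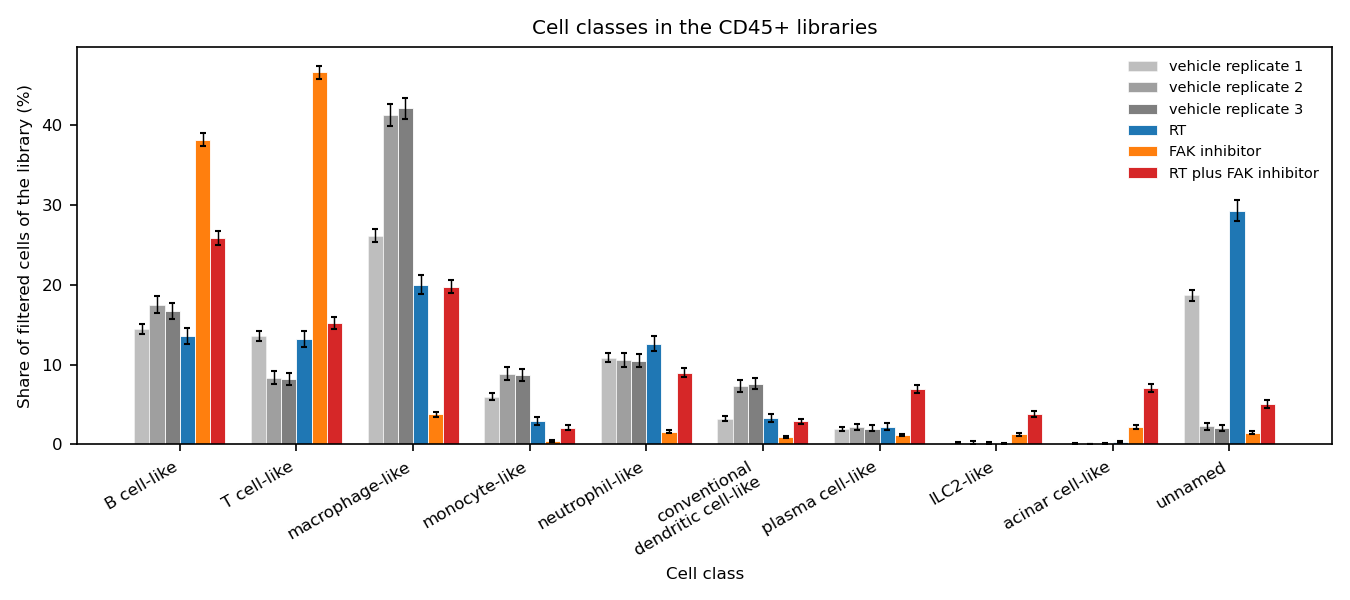
Share of filtered cells (percent, vertical axis) of each cell class in the 6 CD45+ libraries, with 95% exact binomial intervals as error bars. The FAK inhibitor library had 46.6% T-cell-like and 38.2% B-cell-like cells and 3.79% macrophage-like cells.

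RT alone was compared with vehicle first. Of the 28 measured genes of the proliferation list, 1 rose in T-cell-like cells over all genes tested and 13 rose when adjusted over the list alone, with a median log2 fold change of 0.93 (camera adjusted p = 4.22e-30; adjusted p = 0.768 with an estimated correlation). Cdk1, the kinase that drives entry into mitosis, rose by 1.40 ± 0.29 (log2, SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0120), from 18 to 50.7 CPM. Aurkb, a mitotic kinase, had a log2 fold change of 1.34 ± 0.33 (adjusted p = 0.0908) and H2afz one of -0.01. Cdk1 was not called with stricter cells (adjusted p = 0.0973), without vehicle replicate 2 (0.174), with cells split by sex or by DESeq2. Cluster 33, led by proliferation genes, held 18% of the T-cell UMIs after RT, against 8.87% to 14.2% in vehicle, so the mix of T cells also differed.

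A few interferon-stimulated genes rose after RT. In conventional-dendritic-cell-like cells 3 of 26 type I interferon response genes rose (4 adjusted over the list alone; median 0.55; camera adjusted p = 6.91e-09; adjusted p = 0.792 with an estimated correlation). Rsad2 (viperin) rose by 1.66 ± 0.36 (adjusted p = 0.0117) and Isg15, a ubiquitin-like modifier, by 1.49 ± 0.36 (adjusted p = 0.0379), whereas Oas1a had a value of -1.15. The lectin gene Cd209a fell by 2.04 ± 0.48 (adjusted p = 0.0239), and Rnaset2a and Arhgap28 rose by 1.85 ± 0.42 and 1.49 ± 0.35 (adjusted p = 0.0239 for both). Cluster 17, whose top gene was Cd209a, held 37.2% of the dendritic-cell UMIs after RT against 52.5% to 58.3% in vehicle, so the mix of dendritic cells differed. In monocyte-like cells 0 of 27 type I interferon genes passed over all genes with edgeR, 13 had an unadjusted p under 0.05, and 10 passed adjusted over the list alone (median 0.57; camera adjusted p = 5.89e-22; adjusted p = 0.604 with an estimated correlation). Ifit3 was the nearest, at 1.47 ± 0.27 (adjusted p = 0.118). In neutrophil-like cells the heat shock gene Hspa1a fell by 3.24 ± 0.51 (adjusted p = 0.00695), from 565 to 54.5 CPM.

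Across classes, RT changed 7 genes in monocyte-like cells (7 higher), 30 in neutrophil-like cells (27 higher, 3 lower), 28 in T-cell-like cells (24 higher, 4 lower) and 45 in dendritic-cell-like cells (31 higher, 14 lower). In macrophage-like cells the edgeR test called 0 genes, with 121 at an unadjusted p under 0.05, and DESeq2 called 33. Leaving out genes that were 10 times higher in another class of any library compared left 2, 6, 12 and 11 calls in the 4 classes named first. With the 3 vehicle libraries kept apart these classes had 0, 12, 5 and 4 calls, DESeq2 called 7, 12, 7 and 15, without vehicle replicate 2 they had 4, 3, 9 and 70, and without replicate 3 T-cell-like cells had 60. With cells split by sex, both sexes of a library as separate samples, T-cell-like cells had 1 call, monocyte-like 11 and macrophage-like 15. Of the 28 T-cell calls 1 was among them. Adding cluster 40, which held 63 cells in all and was led by markers of another class, left 12 calls in T-cell-like cells, Cdk1 not among them (adjusted p = 0.0956). The log2 fold change of Cdk1 stayed at 1.40, and the prior degrees of freedom that edgeR estimated went from 38.4 to 14.9. Calls therefore depended on that estimate. The histone genes Hist1h1b (higher in T-cell-like cells by 2.74 ± 0.30, adjusted p = 2.09e-07) and Hist1h2ap (lower) belong to a family of related genes, and sharing of reads was not tested. In neutrophil-like cells Lars2 rose by 1.59 ± 0.32 (adjusted p = 0.00249).

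In the fibroblast-like cells, lists outside the random range for RT against vehicle included inflammatory, interferon, dissociation and collagen processing genes. Random genes are drawn independently, so that range covers neither correlation within a list nor spread between libraries. Of all 109 list medians 64 lay outside its central 95%, so lying outside it is weak evidence. The list of inflammatory CAF cytokines had a median log2 ratio of 0.40, above all 10000 random lists matched on expression, with 15 of 18 members higher. Il6, the cytokine that typifies inflammatory CAFs, was 2.29-fold higher (2.24 to 2.34; 68.9 against 158 CPM), the eosinophil chemokine Ccl11 2.40-fold (2.36 to 2.45) and Ptgs2, the prostaglandin enzyme COX-2, 2.66-fold, while Cxcl14 was 1.46-fold lower. Type I interferon genes were higher in 14 of 17 cases, with a median of 0.26, also above all random lists, and none was 2-fold apart. MHC class I genes were higher in 11 of 17 (median 0.22, 99.97th percentile), among them H2-D1 at 1.90-fold, B2m at 1.62-fold and H2-T23 at 2.19-fold, and the chaperone Calr was 1.74-fold lower. Collagen processing genes were lower in 9 of 12 (median -0.48, below all random lists), including Pcolce (1.80-fold), the collagen chaperone Serpinh1 (1.66-fold) and the cross-linking enzyme Loxl1 (1.53-fold). All 7 fibrillar collagen genes were lower, with a median of -0.28 at the 2.07th percentile, or -0.11 between cells of 1 sex.

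The early-response genes that rise during tissue dissociation moved with these groups, with a median of 0.43 (15 of 19 higher) and Zfp36 at 2.40-fold. Between cells of animals of 1 sex the medians were 0.37 for inflammatory cytokines, 0.20 for type I interferon genes, 0.02 for MHC class I, -0.18 for collagen processing and 0.15 for dissociation stress. Macrophage markers had a median of 0.79 over all cells and -0.32 there. The contractile and interferon-gamma medians, -0.25 and 0.16 over all cells, were 0.14 and -0.15 there. Within myCAF-like and iCAF-like cells inflammatory cytokines had 0.18 and 0.30, type I interferon genes 0.16 and 0.21, MHC class I 0.15 and 0.35 and collagen processing -0.27 and -0.72. In all, 37 of 3194 genes were at least 2-fold apart (21 higher, 16 lower), or 1.16%. The balance turned to 12 higher and 23 lower between cells of 1 sex and to 4 and 22 within myCAF-like cells. Between vehicle CD45+ replicate 1 and the sum of replicates 2 and 3 the same measure gave 2.71% to 4.01% in immune classes. With 1 library per group the CAF-gate differences had no replicate check and no p-value.

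FAK inhibitor alone was compared with vehicle next. Of 20 measured granule and early maturation genes 11 rose in neutrophil-like cells (13 rose and 1 fell when adjusted over the list alone). Their median was 1.78 (camera adjusted p = 3.11e-17, and adjusted p = 0.419 with an estimated correlation). Mmp8, neutrophil collagenase, rose by 3.19 ± 0.35 (adjusted p = 3.50e-08), the resistin-like gene Retnlg by 2.93 ± 0.36 (adjusted p = 9.18e-09), Ngp by 2.64 ± 0.36 (adjusted p = 1.52e-07) and the iron-binding protein gene Lcn2 by 2.46 ± 0.36 (adjusted p = 5.63e-07). Prtn3 had a value of -1.35 and was not called. Genes reported for tumour-associated neutrophils went both ways, with 3 of 21 higher and 7 lower (6 and 7 adjusted over the list alone; camera adjusted p = 0.643). Siglecf fell by 2.16 ± 0.39 (adjusted p = 6.53e-05), the angiogenic factor Vegfa by 1.60 ± 0.38 (adjusted p = 0.00297) and Il1a by 1.55 ± 0.39 (adjusted p = 0.00609), while the chemokine Cxcl3 rose by 3.09 ± 0.39 (adjusted p = 1.09e-05). Adgre1 (F4/80) fell by 2.37 ± 0.40 (adjusted p = 1.18e-05). Most neutrophil-like cells came from cluster 15 in this library (67.7%) and from cluster 5 in vehicle. Cluster 36, led by the granule genes Camp, Ngp, Ltf and Lcn2, held 20.7% of the neutrophil UMIs here against 8.62% to 10.5% in vehicle. Genes of other cell types were called too, Cd3g (3.37 ± 0.31, adjusted p = 5.18e-13) and Gimap1 (3.27 ± 0.35) higher and Mrc1 (-5.67 ± 0.69, adjusted p = 6.56e-09) lower, all 3 more abundant in another class.

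In monocyte-like cells 8 of 27 type I interferon genes rose (13 adjusted over the list alone; median 0.80; camera adjusted p = 1.13e-15), and of 20 interferon-gamma genes 7 rose (11 adjusted over the list alone; median 1.20; camera adjusted p = 4.39e-17). For both lists adjusted p = 0.647 with an estimated correlation. Ifit1 rose by 1.99 ± 0.28 (adjusted p = 0.00369) and Ifit3 by 1.94 ± 0.29 (adjusted p = 0.00556). Gbp2 rose by 2.14 ± 0.27 (adjusted p = 0.00185). The value of Iigp1, -0.62, did not pass. Hypoxia and glycolysis genes fell in 3 of 19 cases (6 adjusted over the list alone; median -0.53; camera adjusted p = 5.50e-07; adjusted p = 0.647 with an estimated correlation), among them Bnip3 (-2.79 ± 0.49, adjusted p = 0.0162) and hexokinase 2, Hk2 (-1.61 ± 0.34, adjusted p = 0.0429). Single genes that fell included Nrg1 (-4.12 ± 0.57, adjusted p = 0.0192), from 173 to 11.4 CPM. Ccl24 (-2.28 ± 0.40) and Cd80 (-2.01 ± 0.36) fell too (adjusted p = 0.0192 for both). Calhm6 rose by 3.01 ± 0.36 (adjusted p = 0.00932). The FAK inhibitor library held 70 monocyte-like cells.

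In T-cell-like cells several genes of regulatory T cells and of proliferation fell. Foxp3 fell by 1.21 ± 0.31 (adjusted p = 0.0115) and Ikzf2 (Helios) by 1.45 ± 0.38 (adjusted p = 0.0139). Of 17 regulatory T-cell genes 6 fell (9 fell and 1 rose adjusted over the list alone; median -0.96; camera adjusted p = 7.13e-05; adjusted p = 0.410 with an estimated correlation), and Gpr83 had a value of 1.04. Of 28 proliferation genes 8 fell (10 adjusted over the list alone; median -0.73; camera adjusted p = 2.27e-05; adjusted p = 0.383 with an estimated correlation), including Nusap1 (-1.22 ± 0.31, adjusted p = 0.0112) and Ccnb2 (-1.27 ± 0.31, adjusted p = 0.00690). Cd8a rose by 1.11 ± 0.33 (adjusted p = 0.0413) and Gpr18 by 1.17 ± 0.30 (adjusted p = 0.0119). Cd163l1 fell by 2.32 ± 0.35 (adjusted p = 9.27e-06). Clusters 2 and 21 held 50.5% and 8.95% of the T cells in this library, and cluster 9 held 49.05% to 52.5% in vehicle. Clusters 2 and 9 both scored best as naive or central memory cells, so their split, here and below, need not mark different T cells. Set against other T cells, cluster 9 had Chil3, Ccl6, Il1b and C1qa among its top genes, like macrophage-like cluster 11. Regulatory-like cluster 10 held 9.87% of the T-cell UMIs here against 14.5% to 17.7% in vehicle. Cluster 33, led by proliferation genes, held 37 of 6918 T cells here and 2.5% to 4.5% in vehicle. Lower expression within cells was not separated from fewer such cells. Of 23 effector genes 8 fell (8 adjusted over the list alone; median -1.13; camera adjusted p = 0.00199; adjusted p = 0.383 with an estimated correlation). These 8, among them Gzmb and Ccl4, were all 10 times higher in another class of a library compared, and myeloid cells made up 6.78% of this library against 46.2% to 68.9% in vehicle.

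In dendritic-cell-like cells the replication helicase genes Mcm7 (1.70 ± 0.34, adjusted p = 0.00112), Mcm6 (1.32 ± 0.34, adjusted p = 0.0209) and Mcm5 (1.30 ± 0.34, adjusted p = 0.0230) rose. They belonged to the proliferation list, of which 6 of 27 rose (11 adjusted over the list alone; median 0.82; camera adjusted p = 3.28e-10; adjusted p = 0.470 with an estimated correlation), while Mki67 had a value of -0.37. Il12b, a subunit of interleukin 12, rose by 1.37 ± 0.34 (adjusted p = 0.0147), and Cd80 and Pdcd1lg2 (PD-L2) fell by 1.46 ± 0.42 (adjusted p = 0.0450) and 1.41 ± 0.40 (adjusted p = 0.0449). The maturation list as a whole did not pass, with 1 of 22 genes higher and 3 lower, the same counts adjusted over the list alone, and a median of 0.11 opposite in sign to the camera direction (adjusted p = 0.770). Nrg1 fell by 3.85 ± 0.51 (adjusted p = 2.35e-07) and the vitamin D receptor gene Vdr by 2.66 ± 0.43 (adjusted p = 2.39e-05).

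FAK inhibitor changed 119 genes in monocyte-like cells (89 higher, 30 lower), 702 in neutrophil-like (415 higher, 287 lower), 589 in T-cell-like (64 higher, 525 lower) and 218 in dendritic-cell-like cells (106 higher, 112 lower). In macrophage-like cells edgeR called 8 genes, all higher, and each of the 8 was 10 times higher in another class of a library compared, which left 0. There 1010 genes had an unadjusted p under 0.05, and DESeq2 called 267. Leaving such genes out gave 59, 324, 123 and 77 calls in the other classes, and without vehicle replicate 2 monocyte-like, neutrophil-like and T-cell-like cells had 72, 191 and 312. With cells split by sex these 3 classes had 55, 294 and 177, and macrophage-like cells 31. DESeq2 called 50, 125, 225 and 45 in the 4 classes named first, and with vehicle libraries kept apart dendritic-cell-like cells had 42 and monocyte-like cells 54. Acinar enzyme transcripts stood at 28.3 to 43.0 UMIs per cell in all 5 classes of this library, against 0.0818 to 1.14 in vehicle and 6.96 to 19.6 after RT.

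**Figure D2:**
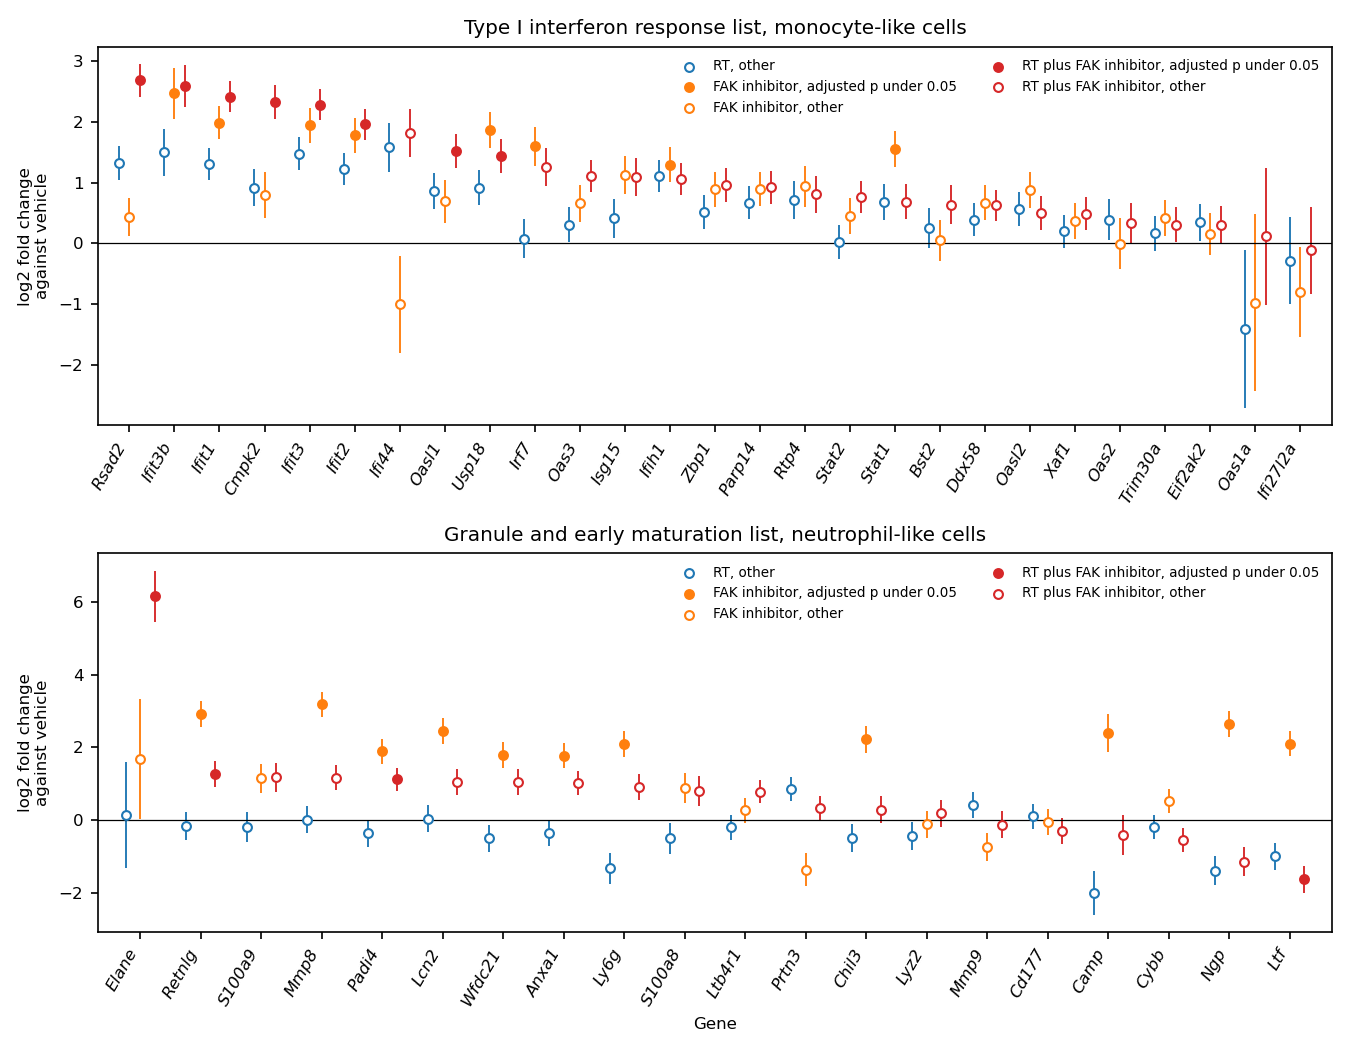
Log2 fold change against vehicle (vertical axis, error bars SE) of each measured gene of the type I interferon list in monocyte-like cells (top) and of the granule and early maturation list in neutrophil-like cells (bottom), with filled points for an adjusted p under 0.05. For FAK inhibitor 8 interferon genes and 11 granule genes rose.

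In fibroblast-like cells the FAK inhibitor library had lower levels of contractile, TGF-beta and matrix genes. Of 12 contractile myofibroblast genes 11 were lower, with a median log2 ratio of -1.15, below all 10000 random lists. The smooth muscle genes Tagln and Acta2 were 4.72-fold (764 against 162 CPM) and 4.09-fold (579 against 142 CPM) lower, and Vim was 1.16-fold higher. The TGF-beta response list was lower in 15 of 18 (median -0.62, below all random lists), with Ccn2 5.29-fold, Tgfb1 itself 3.43-fold and Ltbp2 9.91-fold (9.51 to 10.3) lower, and the co-receptor Tgfbr3 2.5-fold higher. All 7 fibrillar collagen genes were lower (median -0.66, 0.140th percentile), from 6.24-fold for Col11a1 and 1.58-fold for Col1a1 to 1.14-fold for Col3a1. Other matrix genes split, with 15 of 24 lower (median -0.32, 0.0700th percentile): Col8a1 was 10.4-fold (10.2 to 10.6) and Col12a1 9.84-fold (9.66 to 10.0) lower, and Dcn and Col14a1 were 2.23-fold and 2.58-fold higher.

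The list of senescence-associated secretion was lower in 14 of 16 (median -0.97, below all random lists). It included Igfbp3 (8.67-fold, 8.60 to 8.74; 3034 against 350 CPM) and the cell cycle inhibitors Cdkn2b (3.99-fold) and Cdkn2a (3.44-fold). p53 target genes were lower in 16 of 21 (median -0.52, below all random lists). Focal adhesion components were lower in 10 of 17 (median -0.30, 0.0400th percentile), with vinculin, Vcl, 1.72-fold lower. Among genes the naming rule could take, which leaves out haemoglobin, the lowest was Spp1 (osteopontin), 19.1-fold lower (18.7 to 19.4; 1287 against 67.5 CPM), though it was 10 times higher in another class of a library compared, followed by Igfbp2 (14.6-fold), the retinol transporter Stra6 (12-fold), Ddah1 (11.4-fold), Tnfsf8 (10.5-fold) and the cytokine Crlf1 (10.4-fold). Higher genes included Ifi207 (7.12-fold, 6.72 to 7.55), Inmt (6.00-fold), the glutathione transferase Gstm1 (4.94-fold), Clec3b (4.69-fold, 4.63 to 4.75; 166 against 778 CPM), Pcolce2 (4.31-fold) and Ntrk2 (4.23-fold). Complement genes were higher in 5 of 8 (median 0.33, 99.2nd percentile), C4b by 2.05-fold and C3 by 1.55-fold, and Cfb was 2.14-fold lower.

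In all, 224 of 3354 genes were at least 2-fold apart (106 higher, 118 lower), or 6.68%, with 64 higher and 126 lower within myCAF-like cells and 90 and 66 within iCAF-like cells. Between female cells of both libraries the contractile median was -0.94 and the TGF-beta median -0.68, the type I interferon median changed from -0.14 to 0.11, and Mt2 and Fabp4, higher over all cells, had log2 ratios of -0.195 and -0.859. Within myCAF-like cells alone the contractile median was -0.08 and within iCAF-like cells -0.51. The largest fibroblast cluster was 3 after FAK inhibitor (26.3%) and 2 in vehicle (27.8%), with cluster 0 second in both. The myCAF-like clusters 5 and 17 held 1.51% and 0.847% of the cells of this library, against 14.2% and 2.45% in vehicle. Cluster 5 had Spp1, Crlf1, Ltbp2, Stra6 and Col8a1 among its top genes, all far lower here. Clusters 10 and 12 held 12.4% and 8.42% of the cells here and none in vehicle. The iCAF-like cells were 110 of cluster 7 and 151 of cluster 9 here, against 1270 and 3 in vehicle. Within myCAF-like and iCAF-like cells the medians were -0.42 and -0.58 for TGF-beta, -0.38 and -0.84 for fibrillar collagen, -0.36 and -0.43 for senescence-associated secretion, -0.84 and -0.13 for p53, -0.12 and 0.01 for focal adhesion, -0.00 and -0.18 for other matrix and -0.22 and -0.01 for complement genes. Markers of pericytes or smooth muscle had a median of -0.70 (0.13th percentile), -0.56 between female cells and 0.39 within myCAF-like cells, so fewer cells of that type among the fibroblast-like ones were not excluded. Macrophage markers had a median of 1.23. The 3 measured epithelial markers, all more abundant in another class, had a median of -2.08.

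**Figure D3:**
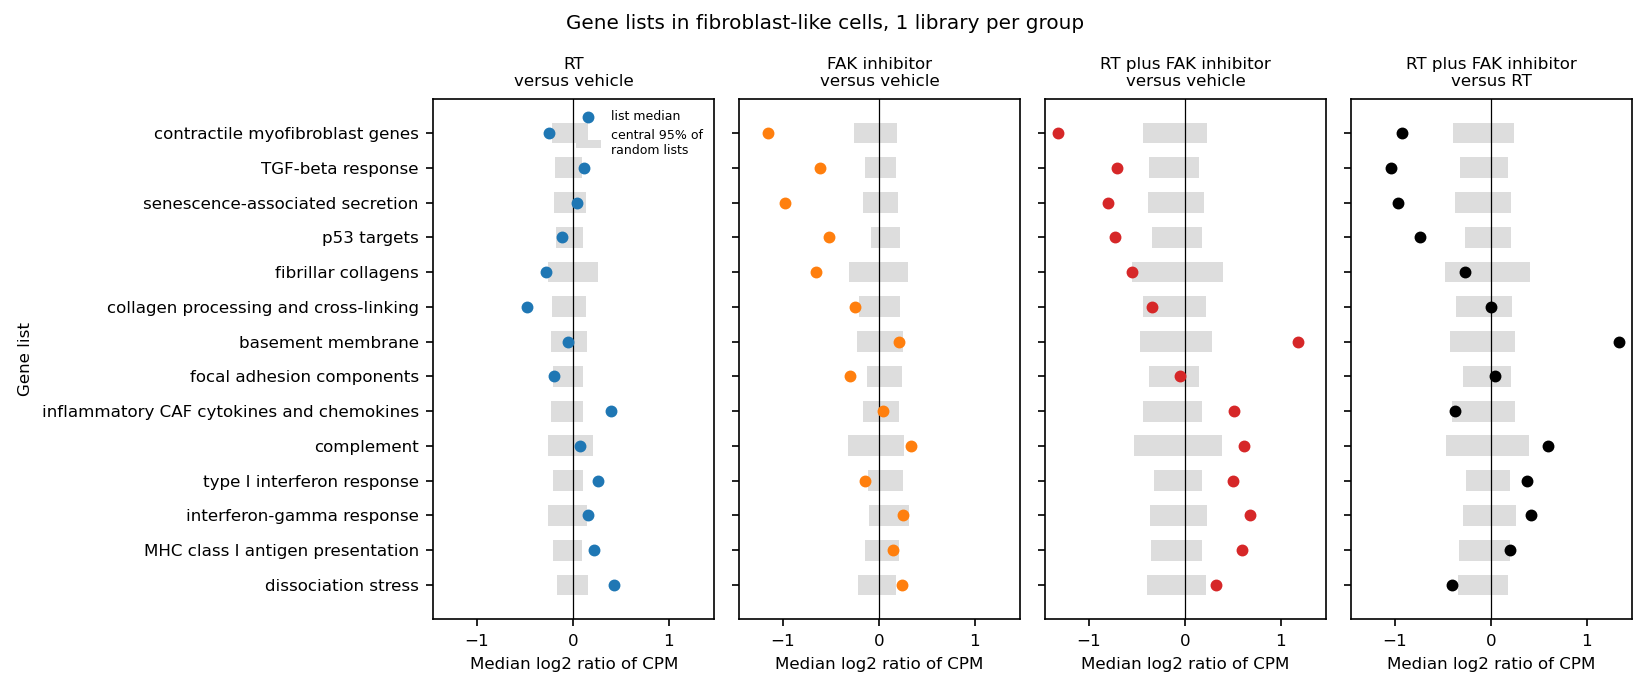
Median log2 ratio of CPM (horizontal axis) of 14 fixed gene lists in fibroblast-like cells for the 4 comparisons, with grey bars for the central 95% of 10000 random lists matched on expression. The contractile list lay at -1.15 for FAK inhibitor and the basement membrane list at 1.18 for RT plus FAK inhibitor against vehicle.

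RT plus FAK inhibitor was compared with vehicle as the combined treatment. In monocyte-like cells 8 of 27 type I interferon genes rose (19 adjusted over the list alone; median 0.96; camera adjusted p = 4.03e-38; adjusted p = 0.765 with an estimated correlation). Rsad2 rose by 2.68 ± 0.27 (adjusted p = 0.000108; 33.4 to 210 CPM), Ifit1 by 2.41 ± 0.26 (adjusted p = 0.000226), Ifit3 by 2.28 ± 0.26 (adjusted p = 0.000448) and Cmpk2 by 2.33 ± 0.28 (adjusted p = 0.000673), and Ifi27l2a had a value of -0.11. Of 20 interferon-gamma genes 2 rose, Irgm1 (1.53 ± 0.26, adjusted p = 0.0128) and Gbp5 (1.79 ± 0.30, adjusted p = 0.0242), and 10 rose and 1 fell adjusted over the list alone (median 0.94; camera adjusted p = 2.11e-14; adjusted p = 0.765 with an estimated correlation). Ccl24 fell by 2.59 ± 0.36 (adjusted p = 0.00325) and Plet1 by 1.65 ± 0.31 (adjusted p = 0.0356).

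In neutrophil-like cells Stfa1, a cystatin of the stefin family, rose by 3.03 ± 0.33 (adjusted p = 1.29e-10), the metalloreductase gene Steap4 by 3.00 ± 0.30 (adjusted p = 4.48e-11), Ifitm1 by 2.51 ± 0.35 (adjusted p = 4.09e-07) and Gbp2 by 2.42 ± 0.34 (adjusted p = 0.000134). Of 26 type I interferon genes 3 rose (6 adjusted over the list alone; median 0.32; camera adjusted p = 0.0245; adjusted p = 0.651 with an estimated correlation), with Ifit1 at 1.97 ± 0.35 (adjusted p = 0.00169). Of 20 granule genes 3 rose and 1 fell (10 and 2 adjusted over the list alone; median 0.80; camera adjusted p = 0.000235; adjusted p = 0.651 with an estimated correlation). Padi4 and Retnlg rose by 1.13 ± 0.32 (adjusted p = 0.0378) and 1.27 ± 0.36 (adjusted p = 0.0442), Elane from 0.286 to 18.9 CPM, and lactoferrin, Ltf, fell by 1.62 ± 0.38 (adjusted p = 0.00536). Hspa1a fell by 2.93 ± 0.50 (adjusted p = 0.00377). Cluster 15 held 91.2% of the neutrophil-like cells of this library.

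In dendritic-cell-like cells the C-type lectin receptor genes Clec4b1 (2.75 ± 0.34, adjusted p = 1.77e-08) and Clec4a2 (1.68 ± 0.34, adjusted p = 0.00108) rose, and Il12b fell by 2.74 ± 0.43 (adjusted p = 1.27e-05; 47.5 to 6.94 CPM). Ccl22, a chemokine of mature dendritic cells, fell by 1.77 ± 0.48 (adjusted p = 0.0348), Aldh1a2, an enzyme of retinoic acid synthesis, by 2.08 ± 0.43 (adjusted p = 0.00156) and Vdr by 2.02 ± 0.39 (adjusted p = 0.000547). Cluster 16, whose top gene was Ccl22, held 31.7% of the dendritic-cell UMIs here against 41.8% to 47.5% in vehicle. Of 22 maturation genes 2 fell (4 adjusted over the list alone; median -0.06; camera adjusted p = 0.0407; adjusted p = 0.601 with an estimated correlation). In T-cell-like cells Avpi1 and the leukotriene B4 receptor gene Ltb4r1 rose by 1.33 ± 0.28 (adjusted p = 0.00830) and 1.27 ± 0.29 (adjusted p = 0.0214), and Rnf213 fell by 1.52 ± 0.35 (adjusted p = 0.0196). Cluster 2 held 54.3% of these T cells and cluster 9 none, where cluster 9 led in vehicle. In macrophage-like cells 0 of 28 proliferation genes passed over all genes with edgeR, 21 had an unadjusted p under 0.05, and 12 were lower adjusted over the list alone (median -1.47; camera adjusted p = 6.14e-25; adjusted p = 0.983 with an estimated correlation), with Pclaf at -2.23 ± 0.29 (adjusted p = 0.277). Cluster 11, with Pclaf among its top genes, held 10.2% to 15.8% of the vehicle macrophage-like cells and 53 cells here. Clusters 4 and 12 held 39.7% and 38.3% here, and cluster 1 held 44.2% to 69.5% in vehicle.

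The combined treatment changed 49 genes in monocyte-like cells (44 higher, 5 lower), 217 in neutrophil-like (175 higher, 42 lower), 94 in T-cell-like (57 higher, 37 lower), 166 in dendritic-cell-like (94 higher, 72 lower) and 11 in macrophage-like cells (11 higher). Leaving out genes 10 times higher in another class left 20, 121, 13, 44 and 0, and DESeq2 called 221 in macrophage-like cells, where 977 genes had an unadjusted p under 0.05. Without vehicle replicate 2 neutrophil-like and T-cell-like cells had 48 and 40 calls, and without replicate 3 T-cell-like cells had 157. With cells split by sex neutrophil-like, T-cell-like, monocyte-like and macrophage-like cells had 69, 25, 31 and 35. DESeq2 called 53, 40 and 44 in neutrophil-like, T-cell-like and dendritic-cell-like cells, and vehicle libraries kept apart gave 144, 31 and 61. Acinar transcripts stood at 86.2 to 128 UMIs per cell in the 5 classes.

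**Figure D4:**
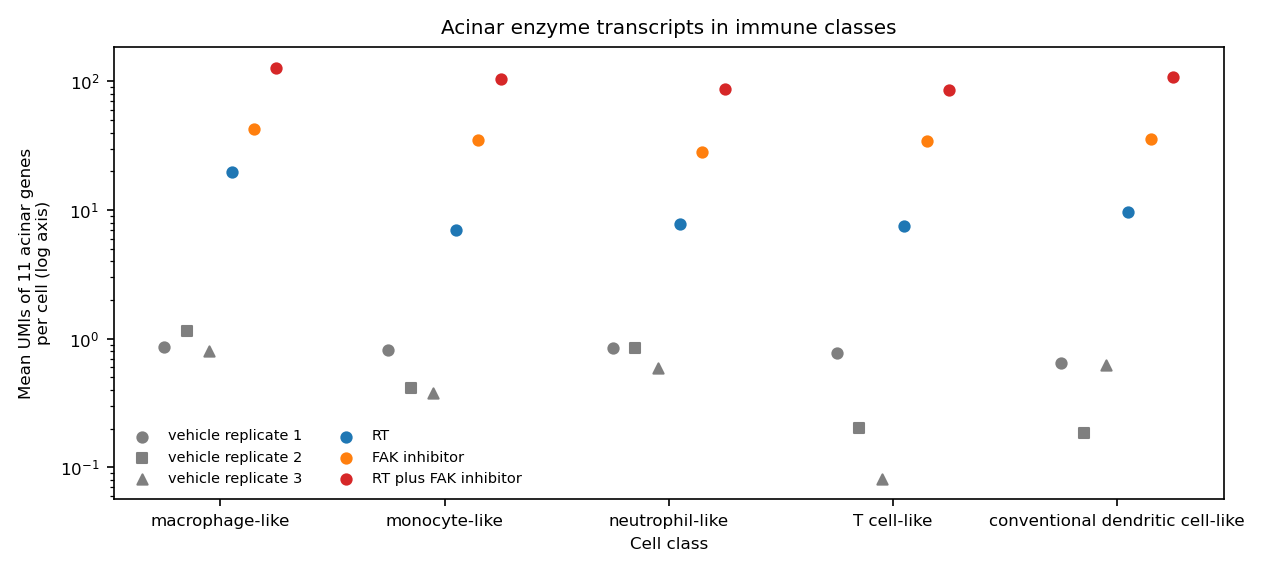
Mean UMIs of the 11 acinar marker genes per cell (vertical log axis) in 5 immune classes of the 6 CD45+ libraries, 1 point per library and class. The RT plus FAK inhibitor library lay at 86.2 to 128 UMIs per cell and the vehicle libraries at 0.0818 to 1.14.

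The fibroblast-like cells of the RT plus FAK inhibitor library stood apart from vehicle in basement membrane, interferon and contractile genes. All 10 basement membrane genes were higher (median 1.18, above all random lists), with nidogen 1, Nid1, at 3.02-fold (293 against 884 CPM) and the laminin chains Lama2, Lamc1 and Lamb1 at 2.65-, 2.5- and 2.45-fold. Type I interferon genes were higher in 17 of 20 (median 0.50, above all random lists), Ifi27l2a by 3.37-fold (218 against 735 CPM), and interferon-gamma genes in 10 of 12 (median 0.68). MHC class I genes were higher in 14 of 17 (median 0.60), with H2-D1 at 2.16-fold and Calr 2.37-fold lower. Inflammatory CAF cytokines were higher in 11 of 17 (median 0.51, 99.95th percentile), Ccl11 by 6.20-fold and Csf1 by 2.30-fold, and Cxcl14 was 4.71-fold lower. Complement genes were higher in 5 of 8 (median 0.61, 99.5th percentile), and C3 by 3.06-fold.

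Contractile genes were lower in 11 of 12 (median -1.32, below all random lists), with Acta2 6.27-fold and Tagln 4.71-fold lower. TGF-beta response genes were lower in 14 of 18 (median -0.70), with Inhba 8.01-fold and Tgfb1 4.99-fold lower and Tgfbr3 4.24-fold higher. p53 targets were lower in 19 of 21 (median -0.73) and genes of senescence-associated secretion in 13 of 16 (median -0.81), with Cdkn2b 10.5-fold and Cdkn2a 9.85-fold lower (215 against 21.8 CPM). Far up among genes the naming rule could take were Smpd3 (36.0-fold, though more abundant in another class) and Plac9b (31.1-fold, 28.2 to 34.3). So were Pcsk6 (17.9-fold), Plau (16.4-fold), Lvrn and Sema3c (15.3-fold each), Ogn (12.5-fold) and Clec3b (10.5-fold). Among the same genes those furthest down were Crlf1 (21.2-fold, 20.1 to 22.3), Wif1 (18.4-fold), Stra6 (17.9-fold), Ddah1 (17.3-fold) and Cyp26a1 (17.1-fold). Spp1 (15.6-fold), Igfbp2 (15.0-fold), Col11a1 (14.5-fold) and Col12a1 (13.8-fold) followed. Markers of other cell types lay further out, with medians of 6.09 (acinar) and -7.17 (erythroid).

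Here 475 of 3351 genes were at least 2-fold apart (238 higher, 237 lower), or 14.2%, with TMM scaling 282 were higher and 204 lower, and within myCAF-like cells 117 and 215. Only 38.3% of the cells of this library were named fibroblast-like, because 59.2% lay in unnamed clusters with few UMIs; without the limit on UMIs 2 of these 3 clusters would be named acinar-like, and counted as fibroblasts all 3 brought the share to 97.49%, and the contractile median was then -1.36. Cells of 1 sex could not be compared with vehicle, and within myCAF-like cells alone the basement membrane and contractile medians were 0.09 and -0.12, against 1.12 and -1.07 within iCAF-like cells. Inflammatory cytokines had 1.13 within myCAF-like and -0.54 within iCAF-like cells, type I interferon genes 0.05 and 0.22, interferon-gamma genes -0.04 and 0.18, MHC class I genes 0.10 and 0.16, and complement genes 0.19 and 0.05. TGF-beta genes had -0.32 and -0.99, p53 targets -0.85 and -0.18 and senescence-associated secretion -0.60 and -1.11. The cells came mainly from clusters 4 (24.6%), 9 (24.5%) and 3 (18.2%) here and from clusters 2 (27.8%), 0 (23.5%) and 5 (14.8%) in vehicle. Epithelial markers had a median of -3.75, pericyte markers -0.90 and macrophage markers 0.56.

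**Figure D5:**
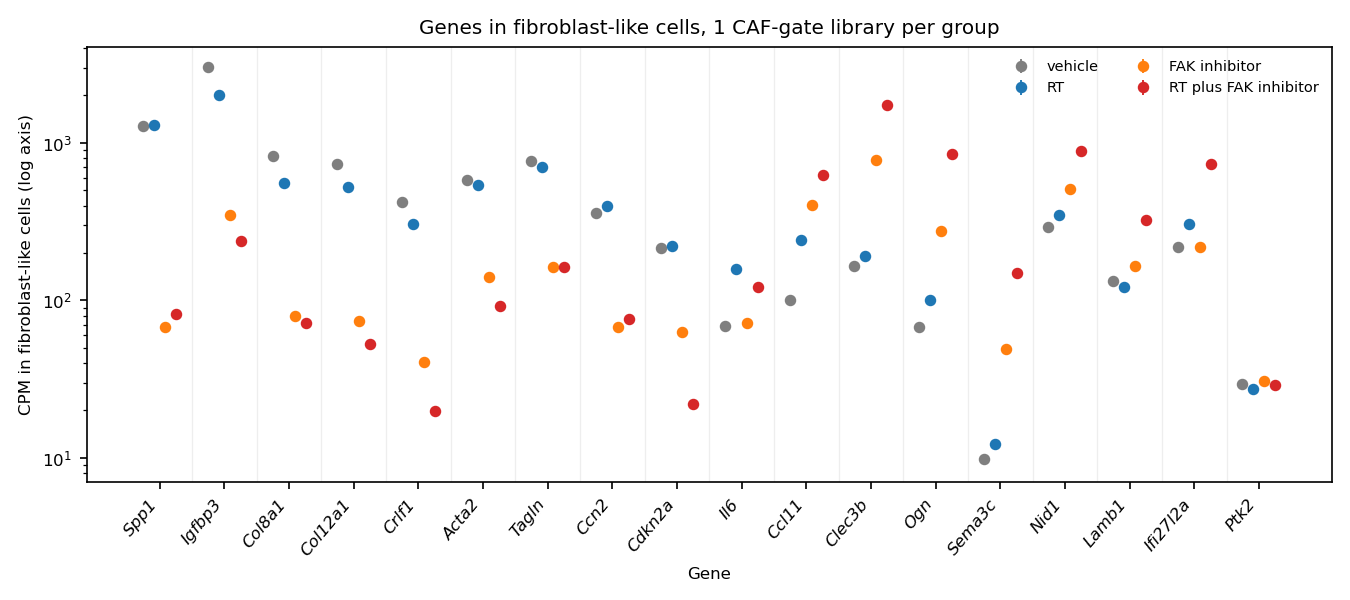
CPM (vertical log axis) of 18 genes in fibroblast-like cells of the 4 CAF-gate libraries, 1 point per library, with 95% exact Poisson intervals that are mostly smaller than the points. Spp1 lay at 1287 and 1295 CPM in vehicle and RT and at 67.5 and 82.4 CPM in the FAK inhibitor and combined libraries.

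RT plus FAK inhibitor against RT asked what the inhibitor added to RT. In T-cell-like cells 1 of 28 proliferation genes fell (15 adjusted over the list alone; median -1.09; camera adjusted p = 6.35e-24; adjusted p = 0.845 with an estimated correlation). The gene that passed was Ccnb2 (-1.43 ± 0.35, adjusted p = 0.0391), which was 10 times higher in another class of a library compared. Cluster 33 held 6.65% of the T-cell UMIs here and 18% after RT. Cd163l1 rose by 2.21 ± 0.38 (adjusted p = 0.000558) and Ltb4r1 by 2.03 ± 0.37 (adjusted p = 0.00183). Cluster 23, with Cd163l1 among its top genes, held 15.0% of T cells here and 4.98% after RT, and cluster 9 held 45.0% after RT and none here. In dendritic-cell-like cells Il12b fell by 3.93 ± 0.48 (adjusted p = 4.31e-08; 116 to 6.94 CPM) and Aldh1a2 by 1.94 ± 0.46 (adjusted p = 0.0142), and Pid1 rose by 2.08 ± 0.43 (adjusted p = 0.00251). Cluster 16, of mature dendritic cells, held 31.7% of the dendritic-cell UMIs here and 62.8% after RT. Of 22 maturation genes 1 rose, the co-stimulatory ligand gene Tnfsf9 (1.81 ± 0.46, adjusted p = 0.0283), and 1 fell (1 and 2 adjusted over the list alone; median -0.58; camera adjusted p = 1.02e-05; adjusted p = 0.572 with an estimated correlation). In neutrophil-like cells the antiprotease gene Slpi rose by 2.38 ± 0.43 (adjusted p = 0.000244), Ifitm1 by 2.39 ± 0.45 (adjusted p = 0.000431), Steap4 by 2.09 ± 0.37 (adjusted p = 0.000223) and Ly6g by 2.24 ± 0.46 (adjusted p = 0.0161). Of 20 granule genes 3 rose (11 adjusted over the list alone; median 1.08; camera adjusted p = 6.50e-10; adjusted p = 0.936 with an estimated correlation). In monocyte-like cells Ccl24 fell by 3.60 ± 0.40 (adjusted p = 0.00112; 161 to 12.5 CPM).

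The calls numbered 17 in monocyte-like cells (15 higher, 2 lower), 97 in neutrophil-like (79 higher, 18 lower), 63 in T-cell-like (45 higher, 18 lower) and 117 in dendritic-cell-like cells (63 higher, 54 lower). Leaving out genes 10 times higher in another class left 1, 53, 18 and 36. edgeR called 0 in macrophage-like cells, with 619 at an unadjusted p under 0.05, and DESeq2 77. Without vehicle replicate 2 neutrophil-like cells had 18 calls and T-cell-like cells 26, against 131 in the latter without replicate 3. With cells split by sex neutrophil-like, T-cell-like and macrophage-like cells had 52, 8 and 13. DESeq2 called 20, 25 and 29 in neutrophil-like, T-cell-like and dendritic-cell-like cells, and vehicle libraries kept apart gave 45, 23 and 16, with 3 in monocyte-like cells. This comparison set 1 library against 1, with the spread taken from the vehicle samples.

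In fibroblast-like cells the inhibitor added to RT went with higher basement membrane genes (10 of 10; median 1.34, above all random lists) and lower TGF-beta response genes (14 of 18; median -1.04, below all random lists), 9 of them at least 2-fold. Contractile genes were lower in 11 of 12 (median -0.92), senescence-associated secretion genes in 16 of 17 (median -0.97) and p53 targets in 19 of 20 (median -0.74). Between cells of 1 sex the medians were 1.28 for basement membrane, -0.85 for TGF-beta, -0.49 for contractile, -0.80 for senescence-associated secretion and -0.55 for p53 genes, and pericyte markers had -0.65 over all cells and -0.86 there, so fewer cells of that type were not excluded. Acta2 was 5.86-fold lower, Plac9b 24.3-fold, Pcsk6 19.7-fold, Sema3c 12.2-fold, the Notch-related gene Dlk1 10.2-fold and Gstp1 10.0-fold higher, and Wif1 23.1-fold, Spp1 15.7-fold, Cyp26a1 15.6-fold and Cdkn2a 10.1-fold lower. Type I interferon genes were higher in 15 of 20 (median 0.38, 99.96th percentile), but the median was -0.051 when only genes of at least 50 CPM were used. Inflammatory cytokines had a median of -0.38, which was 0.93 within myCAF-like and -1.39 within iCAF-like cells. In the same order basement membrane genes had 0.20 and 1.41, contractile genes -0.00 and -0.51, TGF-beta genes -0.43 and -0.96, and type I interferon genes -0.16 and 0.05, and RT cells came mainly from clusters 0, 2 and 7. In all, 390 of 3290 genes were at least 2-fold apart (202 higher, 188 lower), or 11.9%, and with TMM scaling 237 were higher and 163 lower. TMM placed the level of no difference at log2 ratios of -0.02, 0.04, -0.10 and -0.08 for RT, FAK inhibitor and the combination against vehicle and the combination against RT, and the median over all genes lay at -0.03, 0.03, -0.13 and -0.10.

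Whether the effect of RT differed with and without the inhibitor was tested with the interaction term of the same edgeR model. It was called for 220 genes in T-cell-like, 151 in neutrophil-like, 104 in dendritic-cell-like and 3 in monocyte-like cells. It was called for 0 genes in macrophage-like cells by edgeR, where 188 had an unadjusted p under 0.05, and for 16 by DESeq2. Leaving out genes 10 times higher in another class of any library compared left 42, 26, 45 and 0 calls in the 4 classes named first, and without vehicle replicate 2 T-cell-like cells had 77, neutrophil-like 0 and monocyte-like 0. Stricter cells gave 95 in T-cell-like and 15 in neutrophil-like cells, and cells split by sex 0, 24 and 47 in T-cell-like, neutrophil-like and dendritic-cell-like cells. In the same order vehicle libraries kept apart gave 97, 41 and 0, and DESeq2 43, 2 and 9, and both gave 0 in monocyte-like cells.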

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

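Tests of doublets, myeloid loss and naive lymphocytes were chosen after the results were seen, the others after the patterns tested.

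Acinar-like cells made up 2.17% of the FAK inhibitor and 7.04% of the RT plus FAK inhibitor CD45+ library, a gate that should not hold them, against 0.0586% ± 0.0146 in vehicle and 0.285% after RT (8.82% after RT without the limit on UMIs per cluster), and acinar transcripts were found in all 5 tested immune classes of both libraries. Doublets as the only source were argued against by a median of 92 acinar UMIs per macrophage-like cell in the combined library, with at least 1 in 100% of them. An earlier measure, the share of acinar UMIs in the top 5% of these cells (27.8%), lay between the values set for either outcome. RNA of acinar cells carried over into droplets may account for the pattern: acinar genes kept the same proportions in every class, with a largest median log2 deviation of 0.123. The RT library also held 6.96 to 19.6 acinar UMIs per cell, against 0.0818 to 1.14 in vehicle; why was not tested, and treatment and library cannot be separated.

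B-cell-like and T-cell-like cells together made up 84.8% of the FAK inhibitor CD45+ library against 25.0% to 28.0% in vehicle. Lymphoid tissue from 1 animal alone was argued against, since the corrected share was 87.8% among cells with Xist and 88.0% among cells with Y-linked transcripts, a difference of 0.177 percentage points. A loss of myeloid cells alone would raise all other classes alike, but the ratio of T-cell-like to plasma-cell-like cells was 39.8 against 3.89 to 6.99 in vehicle, 5.69 times the highest. Naive lymphocytes of lymphoid tissue or blood could not be excluded: the median log2 fold change of naive and memory genes was 0.38 (0.382; camera adjusted p = 0.00739; adjusted p = 0.583 with an estimated correlation). The estimated correlation could not decide this, since 0 of all 564 list tests passed camera with it. An effect of the inhibitor on lymphocyte numbers stays open as a hypothesis beside naive lymphocytes, with 1 library behind it.

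Contractile genes were lower in fibroblast-like cells of the FAK inhibitor library. Sex of the animals as the cause was argued against by a median log2 ratio of -0.943 between cells with Xist of both libraries. It lay beyond -0.576, a bound set from the all-cell value. Dilution by acinar RNA was argued against too, since acinar genes took 0.0781% of the fibroblast UMIs. Another mix of fibroblast clusters cannot be told apart from lower expression within cells: the median within myCAF-like cells was -0.0774, the value expected of such a mix, but 3 of the list's genes helped to define those clusters. A response to the inhibitor may remain as a hypothesis beside fewer pericyte-type cells, whose markers had a median of -0.70, and animal and library were not separable from it.

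The effect of RT differed with and without the inhibitor, by the interaction term, for 3 genes in monocyte-like, 151 in neutrophil-like, 220 in T-cell-like and 104 in dendritic-cell-like cells. These counts moved with the processing, for example to 2, 24, 0 and 47 with cells split by sex and 0, 41, 97 and 0 with vehicle libraries kept apart. Unnamed cells made up 59.2% of the RT plus FAK inhibitor CAF-gate library, where 57.1% of barcodes had under 2000 UMIs. Without the limit on UMIs per cluster 42.15% of its cells would be named acinar-like and 55.97% fibroblast-like. In the RT CD45+ library 29.3% of cells stayed unnamed, of which clusters 13 and 18 held 16.3% and 8.54% of the library at median UMI counts of 543 and 532. Without that limit, set after seeing the data, they were named macrophage-like and acinar-like. In vehicle 10.4% ± 11.7 were unnamed, mostly in cluster 8 of replicate 1 (14.05%). Among stricter cells RT had 6.34% against 8.26% ± 10.4.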

How the results depend on the processing

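The plan fixed before the data were examined kept the 3 vehicle libraries apart, and summing replicates 2 and 3 was chosen after. Alternatives chosen after seeing the data split cells by sex, left out genes higher in other classes or used 1 fibroblast subclass or 1 sex. Others counted clusters of few UMIs as fibroblasts, counted clusters led by other markers under their best class or dropped the limit on UMIs. The interaction was also recomputed after, beyond size factors and replicates left out. The remaining alternatives were fixed before. No paired analysis was possible because each treated group had 1 library per gate, so the groups shared 1 replicate number. On simulated counts for RT against vehicle a 2-fold change was recovered for 5.97% (macrophage-like) to 31.3% (neutrophil-like) of changed genes and an 8-fold change for 87.9% to 100%. Recovery did not follow depth, since macrophage-like cells were deepest; they had the widest spread (biological coefficient of variation 0.36 against 0.213 in neutrophil-like cells) and the fewest prior degrees of freedom (3.55 against 61.3). What depth alone limited was not separated. The prior degrees of freedom in T-cell-like cells ran from 6.66 with cells split by sex to infinite without a filter on low counts, against 38.4 in the report, and counts of calls depend on that estimate. Of the values for named immune genes over these alternatives, 3590 kept direction and side of the threshold, 1253 lost the call and 3 changed sign. Of those for named fibroblast genes, 252 stayed within their counting interval, 199 moved and 3 changed sign, and of fibroblast list medians 458 stayed, 119 moved and 25 changed sign. Counts not given for an alternative stayed within 1.5 times their value in the report. Except where an alternative tests fewer genes, cells or samples by construction, the cause was not tested.

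Counts in a row below are for RT, FAK inhibitor, the combination, the combination against RT and the interaction, which rows of 4 leave out. The DESeq2 Wald test called these counts of genes. Macrophage-like cells had 33, 267, 221, 77 and 16. Monocyte-like cells had 7, 50, 34, 16 and 0. Neutrophil-like cells had 12, 125, 53, 20 and 2. T-cell-like cells had 7, 225, 40, 25 and 43. Dendritic-cell-like cells had 15, 45, 44, 29 and 9. RLE size factors in place of TMM moved these counts. Dendritic-cell-like cells had 74 for RT and 184 for the combination against RT. Monocyte-like cells had 0 for the interaction. Neutrophil-like cells had 98 for the interaction. Without a filter on low counts more genes were called. Macrophage-like cells had 54, 538, 543, 253 and 46. Monocyte-like cells had 52, 371, 212, 102 and 79. Neutrophil-like cells had 61, 754, 259, 156 and 190. T-cell-like cells had 54, 687, 141, 125 and 278.

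Stricter limits on cells moved counts and shares. Macrophage-like cells had 11, 32, 32, 0 and 0. Monocyte-like cells had 4, 82, 57, 17 and 0. Neutrophil-like cells had 7, 250, 60, 23 and 15. T-cell-like cells had 10, 425, 53, 37 and 95. In percentage points above the vehicle mean, the T-cell-like share became 6.82 for RT and 46.8 for FAK inhibitor. The B-cell-like share became 0.871 for RT, 13.3 for FAK inhibitor and 1.43 for the combination. The neutrophil-like share became 7.78 for RT and -13.4 for FAK inhibitor. For RT, FAK inhibitor and the combination in turn, the plasma-cell-like share became 1.45, -1.33 and 7.59, and the ILC2-like share -0.176, 1.63 and 5.56. The acinar-like share became 0.349, 2.23 and 9.73 in that order. In the CAF gate the fibroblast-like share became 96.7% for vehicle, 95.5% for RT, 98.6% for FAK inhibitor and 55.6% for the combination. The mesothelial-like share became 2.40% for the combination. The acinar-like share became 0.321% for FAK inhibitor and 0.448% for the combination. The unnamed share became 0.132% for RT, 0.110% for FAK inhibitor and 41.5% for the combination.

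Keeping the cells marked as doublets moved counts and shares. Macrophage-like cells had 5, 24, 32 and 3. Monocyte-like cells had 61, 456, 215, 112 and 60. T-cell-like cells had 69, 689, 154, 140 and 300. Dendritic-cell-like cells had 82, 378, 251 and 197. Neutrophil-like cells had 99 for the interaction. In percentage points above the vehicle mean, for RT, FAK inhibitor and the combination, the neutrophil-like share became 2.47, -8.38 and -1.30. The ILC2-like share became -0.119, 1.15 and 3.53. The acinar-like share became 2.20 for FAK inhibitor and 7.78 for the combination. In the CAF gate the fibroblast-like share became 34.6% for the combination. The mesothelial-like share became 1.55% for the combination. The acinar-like share became 0.499% for the combination. The unnamed share became 0.375% for FAK inhibitor and 63.3% for the combination. Drawing equal numbers of cells per class from each library moved these counts. Macrophage-like cells had 8, 21, 25, 0 and 0. Monocyte-like cells had 23, 157, 59, 57 and 33. Neutrophil-like cells had 59 for RT. T-cell-like cells had 9, 148, 49, 37 and 29. Raising the mitochondrial limit to 20% moved shares. In percentage points above the vehicle mean, the neutrophil-like share became -8.53 for FAK inhibitor and -1.35 for the combination. The plasma-cell-like share became 4.74 for the combination. The acinar-like share became 2.05 for FAK inhibitor and 6.92 for the combination. In the CAF gate the fibroblast-like share became 97.3% for FAK inhibitor. The unnamed share became 0.141% for vehicle and 0.468% for FAK inhibitor.

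With the 3 vehicle libraries kept apart as samples, as first planned, the counts that moved fell. Monocyte-like cells had 0, 54, 36, 3 and 0. Neutrophil-like cells had 12, 559, 144, 45 and 41. T-cell-like cells had 5 for RT, 31 for the combination, 23 for the combination against RT and 97 for the interaction. Dendritic-cell-like cells had 4, 42, 61, 16 and 0. With the cells of each library split by sex, and sex as a term, counts moved in both directions. Both sexes of a library were entered as separate samples, so the residual spread lay partly within libraries. The male FAK inhibitor sum of dendritic-cell-like cells held 6766 UMIs. Macrophage-like cells had 15, 31, 35 and 13. Monocyte-like cells had 11, 55, 31, 19 and 2. Neutrophil-like cells had 28, 294, 69, 52 and 24. T-cell-like cells had 1, 177, 25, 8 and 0. Dendritic-cell-like cells had 47 for the interaction. Counting clusters led by other markers under their best class moved 4 counts. T-cell-like cells had 12 for RT, 40 for the combination, 30 for the combination against RT and 138 for the interaction.

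Leaving out genes 10 times higher in another class in every library compared, with the adjusted p-values kept, lowered counts. Macrophage-like cells had 0, 1, 1 and 0. Monocyte-like cells had 2, 91, 28 and 2. Neutrophil-like cells had 8, 580, 150 and 55. T-cell-like cells had 16, 298, 27 and 25. Dendritic-cell-like cells had 24, 138, 95 and 66. Leaving out genes 10 times higher in another class in any library compared lowered them further. Macrophage-like cells had 0, 0, 0, 0 and 0. Monocyte-like cells had 2, 59, 20, 1 and 0. Neutrophil-like cells had 6, 324, 121, 53 and 26. T-cell-like cells had 12, 123, 13, 18 and 42. Dendritic-cell-like cells had 11, 77, 44, 36 and 45.

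Leaving out vehicle replicate 2 or 3 in turn gave these ranges, in which each treated library was still assumed to vary like the vehicle samples. Macrophage-like cells had 0 to 4, 10 to 17, 11 to 19, 0 and 0. Monocyte-like cells had 4 to 11, 72 to 166, 45 to 63, 11 to 24 and 0 to 8. Neutrophil-like cells had 3 to 39, 191 to 683, 48 to 247, 18 to 143 and 0 to 151. T-cell-like cells had 9 to 60, 312 to 704, 40 to 157, 26 to 131 and 77 to 305. Dendritic-cell-like cells had 58 to 70 for RT. The ILC2-like share minus the vehicle mean ranged from -0.166 to -0.140 for RT, 1.04 to 1.06 for FAK inhibitor and 3.57 to 3.59 for the combination percentage points. Without replicate 1 the differences from vehicle became 4.89 (T-cell-like), -3.50 (B-cell-like), -21.7 (macrophage-like) and -4.14 (dendritic-cell-like) percentage points for RT and 6.88 (T-cell-like), -21.9 (macrophage-like) and -4.56 (dendritic-cell-like) for the combination, each over 1.5 times its main value. Without replicate 2 the listed counts of neutrophil-like and T-cell-like cells fell. Leaving out replicate 1 left no residual degrees of freedom, so no test was made.

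Without the limit on UMIs per cluster the macrophage-like share after RT minus the vehicle mean changed sign, from -13.9 to 0.569 percentage points. With clusters led by other markers also counted under their best class it was -2.72. In both cases acinar-like differences became 8.52 for RT, 2.33 for FAK inhibitor and 10.2 for the combination. In the CAF gate without the limit the combination had 55.97% fibroblast-like cells, acinar-like shares were 0.206% for RT, 0.947% for FAK inhibitor and 42.15% for the combination, and unnamed shares were 0.0148% for vehicle, 0.0103% for RT, 0% for FAK inhibitor and 0.00552% for the combination.

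In fibroblast-like cells a minimum of 10 CPM in the higher library gave 87 genes for RT, 552 for FAK inhibitor, 1090 for the combination and 904 for the combination against RT. Within iCAF-like cells alone RT had 96 genes, and within myCAF-like cells alone the combination against RT had 253. Of 109 list medians 64 lay outside the central 95% of random lists, against 42 with a minimum of 50 CPM in either library, where fewer lists could be formed, and 63 with TMM scaling. With that minimum the type I interferon median for the combination against RT was -0.051. Of the 238 gene list tests called with the preset correlation of camera 0 were called with an estimated one, while fry called 1. Changes of sign for named genes came with stricter cells for Ccl24 in dendritic-cell-like cells after RT (-1.28) and for Cd8b1 (-7.32) and Gpnmb (-6.71) in monocyte-like cells after FAK inhibitor, and between cells of 1 sex in fibroblasts for Fabp4 (-0.859) and Mt2 (-0.195) after FAK inhibitor and Fmo2 (-0.710) after RT.

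Signs of list medians outside the random range changed as follows, by alternative. Between cells of 1 sex RT had 0.14 for contractile, -0.15 for interferon-gamma and -0.32 for macrophage marker genes, and FAK inhibitor 0.11 for type I interferon genes. Within myCAF-like cells RT had -0.00989 for interferon-gamma and -0.61 for macrophage marker genes. FAK inhibitor had 0.28 for T-cell-attracting chemokines, 0.0298 for hypoxia and glycolysis, -0.22 for complement and 0.39 for pericyte markers there. The combination had -0.0363 for interferon-gamma and -0.0143 for dissociation stress, and against RT -0.16 for type I interferon and 0.0704 for hypoxia and glycolysis. Within iCAF-like cells RT had -0.0185 for TGF-beta response. FAK inhibitor had 0.0134 for focal adhesion, 0.33 for type I interferon, -0.16 for dissociation stress, -0.0114 for complement and 0.78 for erythroid markers there. The combination had -0.54 for inflammatory cytokines and -0.32 for dissociation stress, and against RT -0.23 for interferon-gamma and -0.19 for complement.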

Other observations

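The gene lists in this part were fixed before the results were seen, but which of them to describe was chosen after, as were Retnla, Ccl8, the haemoglobin genes and the cluster described last.

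In neutrophil-like cells of the FAK inhibitor library, 3 of 17 interferon-gamma response genes rose against vehicle (6 adjusted over the list alone; median 1.09; camera adjusted p = 1.75e-05; adjusted p = 0.419 with an estimated correlation). Gbp2 rose by 2.46 ± 0.37 (edgeR adjusted p = 0.000114) and Igtp by 1.09 (adjusted p = 0.0284). Of 19 MHC class I genes 5 rose (7 adjusted over the list alone; median 0.52; camera adjusted p = 0.00103; adjusted p = 0.419 with an estimated correlation), with the peptide transporter gene Tap1 at 1.19 (adjusted p = 0.00842).

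In macrophage-like cells of the same library Retnla, a marker of alternative activation, had a log2 fold change of 3.81 ± 0.28 that did not pass (adjusted p = 0.0860), from 260.3 to 308.6 CPM in the vehicle libraries to 4484 CPM. Cluster 12, whose top gene was Retnla, held 42.2% of the macrophage-like cells of that library and 58, 60 and 53 cells in the vehicle libraries. After RT the chemokine gene Ccl8 had 2.83 ± 0.27 in these cells (adjusted p = 0.343).

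Markers of other cell types differed between the fibroblast sums. Haemoglobin genes stood at 73.2 (Hbb-bs), 27.3 (Hba-a1), 25.3 (Hba-a2) and 15.5 CPM (Hbb-bt) in the vehicle CAF-gate library and at most 0.0605 CPM after RT or FAK inhibitor. Acinar genes took 0.00905%, 0.00830%, 0.0781% and 0.183% of the UMIs of fibroblast-like cells in vehicle, RT, FAK inhibitor and combined libraries. Pericyte markers had medians of -0.70 for FAK inhibitor (0.13th percentile of random lists) and -0.90 for the combination (0.160th) against vehicle. Macrophage markers, among them Apoe, Gpnmb and Trem2, had 1.23 for FAK inhibitor (1.14 between female cells). For RT they had 0.79 (-0.32 between cells of 1 sex) and for the combination 0.56.

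A macrophage-like cluster led by Ctsk, Mmp9, Acp5 and Atp6v0d2, genes that osteoclasts also express, held 70 cells, all from the RT plus FAK inhibitor CD45+ library. A cluster found in 1 library cannot be told apart from an effect of that library.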
